A study of Mus musculus with 2 samples.

How the data were processed

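Single-cell RNA-seq was made from live CD45+ cells, the surface marker shared by leukocytes, sorted from the colon of 9-month-old female mice. 5XFAD mice carry human transgenes with familial Alzheimer disease mutations, and their wild-type (WT) littermates served as controls. Per the labels, cells of 3 mice were pooled into 1 library per genotype with the 10x Chromium 3′ v3.1 chemistry. Per the submitters' processing notes, Cell Ranger 6.0.1 and the mm10 genome were used; the filters that followed are not given in the sources used here.

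The deposited expression table holds natural log values, ln(1 + counts per 10000 UMIs), for 32285 genes in 6886 cells, and a deposited metadata table gives the UMI count, the number of genes detected, the percent of mitochondrial UMIs and a cluster number from 0 to 16 for each cell. Raw counts were recovered by inverting the log with the deposited total count per cell: 100% of 11758401 nonzero values were whole within 1e-06, and the recovered counts summed to the deposited total in 6886 of 6886 cells. A deposited SCT table of 14128 genes also holds natural log values; its totals matched each library's own median depth (5207 and 4937), so it was used only after scaling by class totals, as an alternative. The metadata name the libraries AD and WT, and AD was taken as 5XFAD because it is the only library that is not WT.

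Both libraries hold exactly 3443 cells. They hold 18604847 UMIs (5XFAD) and 17939499 UMIs (WT), with medians of 5209 and 4938 UMIs and 1668 and 1679 genes per cell. The highest number of genes per cell was 2498 in 5XFAD and 2697 in WT, and 106 WT cells but 0 5XFAD cells had 2500 genes or more, so the upper limit on genes per cell differs between the libraries.

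The deposited metadata hold cluster numbers and no cell type names, so clusters were named from marker lists that, like the gene lists and the rule for named genes, were fixed before the data were examined. Clusters 0 to 5 form the B cell-like class. Clusters 8, 9, 10, 12, 13 and 16 were called regulatory T cell-like, ILC2-like, T cell-like, NK or ILC1-like, gamma delta T cell-like and ILC3-like; clusters 6, 7, 11, 14 and 15 are compared by number. The leading 10 genes of each cluster were checked for markers of other classes. Cluster 5 is led by Hspa1a, Hspa1b and Jun, which themselves differ between the libraries, so cluster sizes within the B cell-like class are not read as cell type shares.

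UMIs were summed per class and library, scaled to CPM by the class total of UMIs, and compared as a log2 ratio of 5XFAD over WT. With 1 pooled library per genotype there is no replicate check: no test was made between genotypes, and the 95% intervals (exact conditional binomial for ratios, Clopper-Pearson for shares) cover counting error only. They do not cover differences between mice or preparations. Where a library had 0 UMIs, a floor of 3 counts over the class gave a bound. Genes with at least 50 UMIs over both libraries entered rankings and lists. The genes named are, in each of the 6 classes with the most cells in their smaller library, the 4 higher and the 4 lower in 5XFAD whose interval bound nearest no change lay farthest from it, among genes with at least 50 CPM in the higher library and at least 20% of their highest class CPM there. Immunoglobulin and T cell receptor variable, diversity and joining segments, ribosomal protein genes, mitochondrially encoded genes, Gm-numbered and Rik models and sex-linked genes were left out. The 4 most extreme members of each gene list in the direction of its median are named too, and Cxcr4, Igha, Ighm, Xist, App and Thy1 are among those named whatever their value. Some genes that the rule selects are not reported here and were not replaced by others. Gene lists with at least 5 measured members were summarised by their median log2 ratio and its percentile among 10000 random lists of the same size matched on expression in 20 bins, as a description of these libraries.

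Shares of cells with a UMI were compared after thinning each cell to 3000 UMIs, which left out 60 cells of 5XFAD and 124 of WT. The plan was to compare heavy chain isotypes in plasma cells, but only 1 cell in 5XFAD and 3 cells in WT had over 10% immunoglobulin UMIs. Isotypes were therefore called in cluster 6, from cells with at least 3 constant region UMIs of which over 50% were of 1 isotype. The procedures were tested on simulated counts with 200 changed genes per class: in the B cell-like class (9681 genes) 95.6% of intervals held the true ratio, and 97.0% of genes changed by 1 on the log2 scale and 100% of those changed by 2 had an interval on the right side of no change. In the other main classes 85.0% (cluster 7) to 95.0% (cluster 6) of genes changed by 1 and at least 99.0% of those changed by 2 did. The simulated class totals varied by counting error alone, with no spread between cells. They therefore check the calculation and not whether the intervals hold where a few cells carry most UMIs of a gene.

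Doublet calling could not be used. Scrublet as shipped with scanpy called very few cells, and a reimplementation of its method, written after that result, called 20 of 6886 cells (0.29%). The planned removal of called doublets was therefore replaced, after the data had been seen, by removal of the cells with the highest doublet scores (306 cells, at most 5% per library). The planned stricter filter (at least 500 genes and at most 10% mitochondrial UMIs) removed 0 cells. Other alternatives were median-of-ratios and TMM scaling, a total without immunoglobulin genes, thinned cells, equal weight per cell, SCT values, other UMI minimums, other denominators and an independent Leiden clustering (30 components, 2000 variable genes, 15 neighbours, resolution 1). A common limit of 2500 genes, removal of cluster 5, removal of the top cell for each gene, centring on the other classes and random lists matched on transcript length as well as expression were added after seeing the data. Gene positions are from GENCODE vM21 on GRCm38, the assembly also called mm10. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2, scikit-image 0.26.0 and matplotlib 3.10.9 were used.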

Results

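Colon CD45+ cells of 5XFAD and WT mice were profiled in 1 library each, pooled from 3 mice, with 3443 cells and 18604847 UMIs in 5XFAD and 3443 cells and 17939499 UMIs in WT. The comparison addresses how gene expression in colon immune cells differs between 5XFAD mice and WT littermates. As each genotype is 1 library, every difference below compares 2 libraries, and intervals cover counting error only.

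Most cells in both libraries were of the B lineage. B lineage cells made up 77.1% of the 5XFAD library (95% interval 75.7 to 78.5) and 80.7% of the WT library (79.3 to 82.0), a log2 share ratio of -0.06 (-0.14 to 0.01). The ratio interval does not use the library size as a limit on the counts, so it is too wide for a class this large. The intervals of the 2 shares do not overlap. T lineage cells made up 14.5% (13.3 to 15.7) of 5XFAD and 12.1% (10.98 to 13.2) of WT cells, and innate lymphoid and NK cells 7.44% (6.58 to 8.36) and 6.19% (5.40 to 7.04). Cluster 6, led by Igha, Jchain, Ighg2b and Iglc1, held 4.82% (4.13 to 5.59) of 5XFAD and 3.31% (2.74 to 3.96) of WT cells, a log2 ratio of 0.54 (0.19 to 0.90). Gamma delta T cell-like cells held 2.21% (1.74 to 2.76) and 1.42% (1.05 to 1.88), a log2 ratio of 0.63 (0.10 to 1.18). Regulatory T cell-like, ILC2-like, NK or ILC1-like and ILC3-like cells had ratios of 0.22, 0.26, 0.21 and 0.56, with intervals that held 0. The shares sum to a whole, and sorting and an equal number of cells per library limit them to relative amounts. The T lineage ratio was 0.27 (0.08 to 0.46), and without the B cell-like class in the denominator it was 0.01. With that denominator the ratios of cluster 6 and gamma delta T cell-like cells were 0.29 (-0.06 to 0.65) and 0.38 (-0.16 to 0.93).

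**Figure D1:**
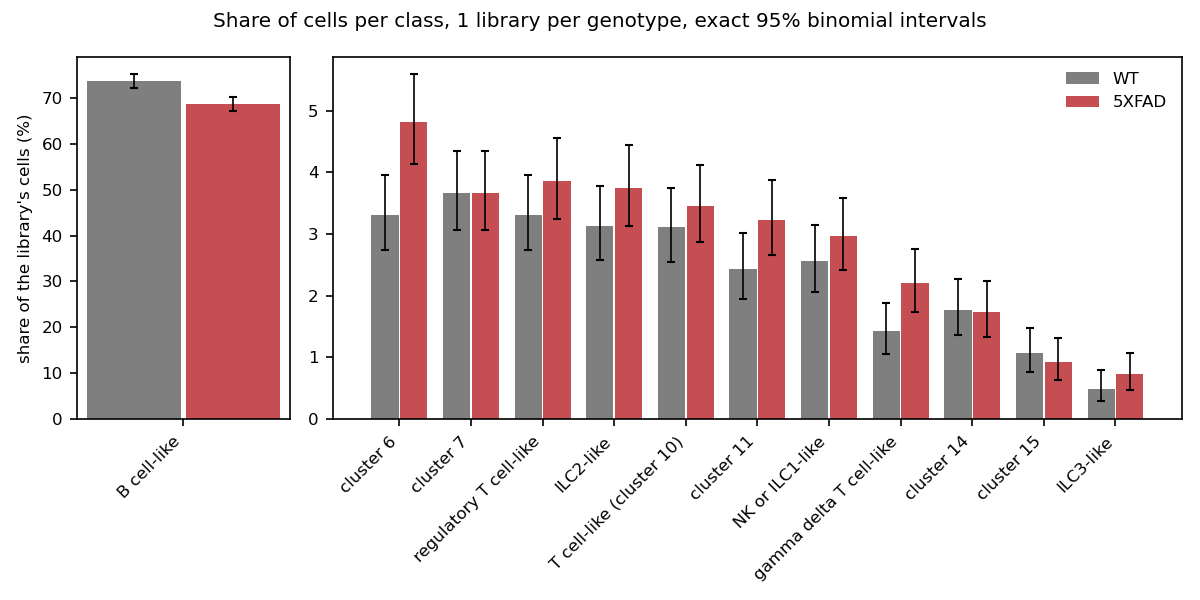
Share of each library's cells (%, y axis) per class (x axis) in WT (grey) and 5XFAD (red), 1 library each; error bars are exact 95% binomial intervals and the B cell-like class has its own axis. B cell-like cells were 73.7% of WT and 68.7% of 5XFAD cells, and each other class was under 5% of either library.

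In B cell-like cells (2364 in 5XFAD and 2538 in WT), heat shock and immediate early genes were lower in 5XFAD. Hspa1a, an inducible HSP70 chaperone (GRCm38 chromosome 17, 34969190 to 34972156), was at 16.7 CPM against 108 in WT, a log2 ratio of -2.69 (-2.91 to -2.48). Its neighbour Hspa1b (chromosome 17, 34956436 to 34959238) had a ratio of -2.53 (-2.72 to -2.34); the pair is nearly identical in sequence, so the split of reads between them is uncertain. Few cells had a UMI of either gene: 38 of 5XFAD and 325 of WT for Hspa1a, and 43 and 405 for Hspa1b. Both ratios therefore rest on a small part of the class. Without the top cell of each library the Hspa1a ratio was -3.19. Jun, a subunit of the AP-1 transcription factor (chromosome 4, 95049034 to 95052222), was at 69.9 against 406 CPM (-2.54, -2.64 to -2.43), and Hsph1 and Fosb had ratios of -1.88 and -2.12. Of the 29 measured members of the immediate early and dissociation list 21 were lower, with a median of -0.49, below every random list drawn (percentile 0). The median was -0.30 without cluster 5, which held 119 cells of 5XFAD and 396 of WT, while cluster 1 held 645 and 471. Clustering without alignment split the B cells mostly by library, with 1297 cells of 5XFAD and 54 of WT in 1 cluster and 103 and 1047 in another, so the B cell-like values compare libraries that differ broadly. The same list had medians of -0.44 in cluster 7, -0.02 in cluster 6, -0.10 in regulatory T cell-like, 0.05 in ILC2-like and -0.09 in T cell-like cells.

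Interferon-related genes were also lower in 5XFAD B cell-like cells. The median of 16 interferon gamma response genes was -0.75 (percentile 0), with Ciita, the master regulator of MHC class II genes, at -1.78 (-1.91 to -1.65), Irf8 at -0.94 and Cd274 at -0.83. The median of 18 type I interferon response genes was -0.60 (percentile 0.01), with Ifi203 at -0.85, Stat2 at -0.98 and Ddx58 at -0.90. Ciita is also among the leading 10 genes of clusters 0 and 5, and cluster 5 held 119 cells of 5XFAD and 396 of WT. The Ciita ratio without cluster 5 is not given here. Without cluster 5, 20 list medians of this class stayed within the SD of random medians. The 2 that moved were the trafficking and immediate early lists, so both interferon medians stayed. The MHC class II list, of which Ciita is a member, did not follow Ciita. Of its 13 genes 8 were higher, with a median of 0.12 (percentile 84.6), and H2-Eb1 and H2-Ab1 both had ratios of 0.42. In the T cell-like cells of cluster 10 the type I interferon list went the other way, with a median of 0.40 (percentile 99.9) and Ifit1 at 1.17 (0.28 to 2.13) and Irf7 at 0.58. In ILC2-like cells all 7 measured interferon gamma genes were higher in 5XFAD, with a median of 0.43 (percentile 98.97). B cell activation genes had a median of -0.28 in B cell-like cells (percentile 1.86), with Egr3 at -1.42, Cd69 at -1.27 and Cd22 at -1.20. The mouse orthologues of Alzheimer disease risk genes had a median of -0.40 (percentile 0.1), with Ptpn6 at -1.37 and Rin3 at -1.59. The median log2 ratio of all genes in this class was -0.12, so these values shift up by 0.12 under median-of-ratios scaling, to -0.63 for interferon gamma, -0.48 for type I interferon, -0.36 for immediate early, -0.16 for B cell activation and -0.28 for risk gene orthologues. Over the 9078 genes of this class with a known transcript length the log2 ratio fell with length (Spearman rho -0.336). Relative to random lists matched on length and expression, a comparison chosen after seeing the data, the medians were -0.60 for interferon gamma, -0.47 for type I interferon and -0.39 for immediate early (percentile 0 each), -0.20 for B cell activation (percentile 2.02) and -0.25 for risk gene orthologues (percentile 0.55).

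Genes higher in 5XFAD B cell-like cells included Atp5md, a subunit of the mitochondrial ATP synthase, at 642 against 247 CPM (1.38, 1.32 to 1.44), Rnaset2a (1.41, 1.30 to 1.51) and Ost4 of the oligosaccharyltransferase complex (1.35, 1.24 to 1.45). Atp5md was also among the named genes of cluster 6 (1.05), regulatory T cell-like (1.18) and ILC2-like cells (1.16). Of 38 nuclear oxidative phosphorylation genes 36 were higher in B cell-like cells, with a median of 0.42 (percentile 100), and the list's median was 0.27 to 0.48 in the other main classes. These genes have short transcripts, with a median length of 565 bases against 2112 for all genes. The B cell-like median lay 0.46 above random lists matched on expression and 0.30 above lists matched on length as well. Under median-of-ratios scaling the B cell-like median was 0.55. Apoe, which encodes a lipid-binding protein, had a ratio of 0.88 (0.83 to 0.93) in B cell-like cells and 1.90 (1.22 to 2.63) in regulatory T cell-like cells. The disease-associated microglia list that holds it had medians of 0.09 (percentile 90.5) and 0.15 (percentile 85.8) there. Apoe leads the markers of cluster 4 of the B cell-like class, which held 285 cells of 5XFAD and 240 of WT.

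**Figure D2:**
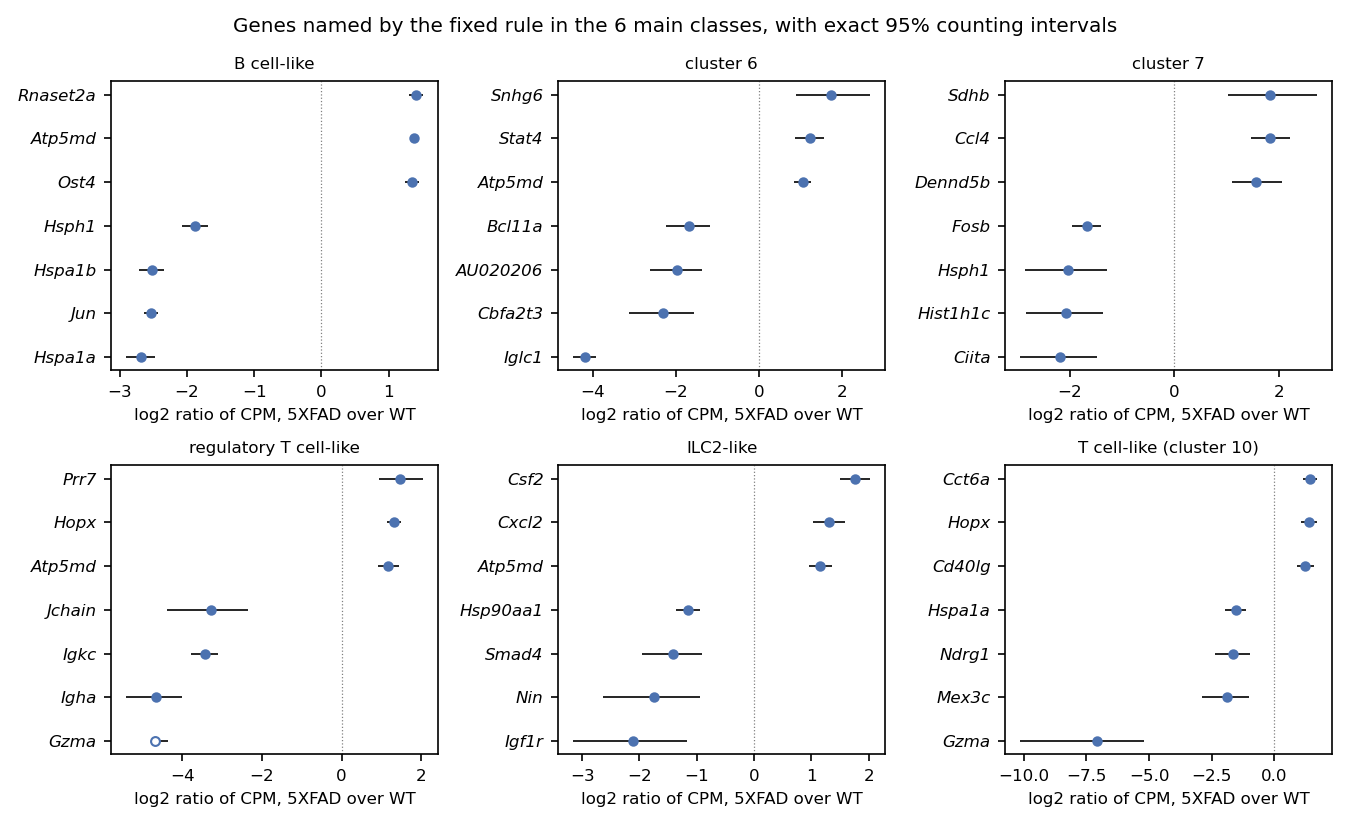
Log2 ratio of CPM, 5XFAD over WT (x axis), of genes named by the fixed rule (y axis) in the 6 main classes; points are ratios, lines exact 95% counting intervals, and the open circle is a bound from a library with 0 UMIs. Atp5md lies at 1.38 and Hspa1a at -2.69 in B cell-like cells.

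Lymphocyte trafficking was examined with Cxcr4, the receptor of the chemokine CXCL12 (chromosome 1, 128588199 to 128592293). Cxcr4 was at 210 CPM in 5XFAD and 274 CPM in WT B cell-like cells, a log2 ratio of -0.39 (-0.46 to -0.31), -0.26 under median-of-ratios scaling and -0.22 without cluster 5. After thinning, 41.8% (39.8 to 43.8) of 5XFAD and 48.0% (46.1 to 50.04) of WT B cell-like cells had a Cxcr4 UMI, and 56.3% and 62.8% before thinning. ILC2-like cells had shares of 14.7% and 16.04% after thinning and 20.9% and 27.8% before, and T cell-like cells of cluster 10 had 18.97% and 17.8% after and 25.2% and 23.4% before. Median depths before thinning were 5086.5 and 4783.5 UMIs in B cell-like and 5559 and 6268.5 UMIs in ILC2-like cells. Cxcr4 ratios were 0.28 (-0.00 to 0.57) in cluster 6, -0.03 in cluster 7, 0.27 in regulatory T cell-like, -0.73 (-1.32 to -0.16) in ILC2-like and 0.43 (-0.10 to 0.97) in T cell-like cells. Of 16 measured trafficking genes 12 were lower in B cell-like cells, with a median of -0.33 (percentile 1.22), or -0.20 under median-of-ratios scaling; Itga4 had a ratio of -0.55, Cxcr5 of -0.46 and Cd69, which retains lymphocytes in tissue, of -1.27, while S1pr4 (0.63), picked after its value was seen, was higher.

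Antibody genes were lower in 5XFAD outside as well as inside the B lineage. Ighm was at 960 against 1508 CPM in B cell-like cells (-0.65, -0.69 to -0.62), at -0.68 in cluster 6 and -0.75 in cluster 7, and at -1.05, -0.99 and -1.98 in regulatory T cell-like, ILC2-like and T cell-like cells, which should lack it. Relative to the median ratio of the other classes with at least 20 UMIs of the gene, Ighm was at 0.37 in B cell-like cells. It was at 0.34 in cluster 6 and 0.27 in cluster 7, so Ighm fell less there than the median of the other classes. Those include classes that should lack Ighm, so these values do not show more Ighm in 5XFAD B lineage cells. The antibody secretion list had a median of -0.51 in B cell-like cells (percentile 0.05), with Igha at -1.10 and Jchain at -1.19. Igha was at 27.1 CPM (5XFAD) and 58.2 CPM (WT) there, no higher than the 27.3 and 234 CPM of T lineage cells. In the WT T lineage 1 cell held 409 of the 559 Igha UMIs. The Igha ratio in B cell-like cells is thus not set apart from background. In cluster 6 Iglc1 had a ratio of -4.20, but 1316 of its 1503 WT UMIs were in 1 cell, and without the top cell of each library the ratio was -1.55. Igha in cluster 6 had a ratio of -0.53, and -1.57 without the top cells, which held 1508 of 1752 UMIs in 5XFAD and 1258 of 1763 in WT. In regulatory T cell-like cells Igha (-4.67), Igkc (-3.43) and Jchain (-3.29) likewise became -1.75, -1.02 and -1.37. Of cluster 6 cells with a called isotype, 29 of 126 in 5XFAD (23.02%, 15.99 to 31.4) and 30 of 98 in WT (30.6%, 21.7 to 40.7) were IgA, 53.2% and 49.0% were IgM, and 15.9% and 12.2% were IgG2b; all 3 pairs of intervals overlapped. As background, 28 of 499 T lineage cells in 5XFAD and 80 of 415 in WT also gave a call. Only 1 and 3 cells were plasma-like, too few to compare.

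In cluster 6, Stat4 (1.22, 0.88 to 1.58) and the noncoding Snhg6 (1.73, 0.89 to 2.68) were higher in 5XFAD, and Cbfa2t3 (-2.32), AU020206 (-1.98) and Bcl11a (-1.69, and 0.054 relative to the other classes) were lower. In cluster 7, led by Egr1, Egr3, Egr2 and Myc, the chemokine gene Ccl4 was at 418 against 117 CPM (1.83, 1.47 to 2.21; 1.46 without the top cells) and Ccl3 had a ratio of 1.61. Ccl4 UMIs were in 15 cells of 5XFAD and 17 of WT, and 1 cell held 121 of the 302 5XFAD UMIs. Sdhb (1.83) and Dennd5b (1.56) were higher too, and Ciita (-2.19), Hist1h1c (-2.07), Hsph1 (-2.04) and Fosb (-1.68) were lower.

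In regulatory T cell-like cells, genes of the regulatory programme were higher in 5XFAD: 13 of 18 members, with a median of 0.34 (percentile 99.8). By the interval bound nearest no change, the inhibitory receptors Tigit (1.61, 0.75 to 2.55) and Ctla4 (0.74, 0.60 to 0.87) led it, with Tnfrsf4 (0.54) and Ikzf4 (1.23). In the same cells the MHC class II list had a median of -1.09, with 4 of 5 members lower. The antibody secretion list had a median of -0.75, with 7 of 8 lower (percentile 0 for each list). Both lists hold B cell genes, and 1 WT cell of this class had 17.1% immunoglobulin UMIs. A set of 7 B cell transcripts, H2-Aa among them, had a log2 ratio of -1.33 in T lineage and innate lymphoid cells together. Both medians are therefore not set apart from B cell RNA or doublets in these cells. Hopx had a ratio of 1.31 (1.13 to 1.48), no more than in the other classes (-0.059 relative to their median), Prr7 of 1.48 and Gzmb, a cytotoxic protease, of 1.72 (1.25 to 2.21). Gzma had 0 UMIs in 5XFAD and 74 in WT. It was 25.9-fold lower with the floor of 3 counts, and the upper end of its log2 interval was -4.36. The WT UMIs came from 3 cells and 57 of them from 1 cell, and without that cell the log2 value with the floor was -2.58. In the T cell-like cells of cluster 10, Hopx (1.37), Cct6a (1.42), Cd40lg (1.22, and -0.28 relative to the other classes) and Ctla4 (1.003) were higher, and 7 of 9 type 3 genes were higher with a median of 0.44 (percentile 99.9), among them Batf (1.33) and Il17f (1.17). All 6 measured MHC class II genes were lower in these cells, with a median of -1.40 (percentile 0). The same limit applies to this median, which is not set apart from B cell RNA or doublets. Gzma was at 2.83 against 386 CPM there (-7.09, -10.15 to -5.22), from 2 cells in 5XFAD and 10 in WT; Mex3c (-1.89) and Ndrg1 (-1.66) were lower. Hspa1a had a ratio of -1.55, which was 0.04 without the top cell of each library.

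ILC2-like cells had more Csf2, which encodes the cytokine GM-CSF, in 5XFAD: 756 against 224 CPM (1.76, 1.496 to 2.03), with UMIs in 65 and 46 cells. Relative to the median of the other classes this ratio was -1.12. Cxcl2 had a ratio of 1.31 (1.03 to 1.59), Calca of 0.79 and Il4 of 0.60, while the type 2 list as a whole had a median of 0.08 (percentile 74.5). Cxcl2 UMIs were in 28 cells of 5XFAD and 29 of WT, and 1 cell held 101 of the 406 5XFAD UMIs. Without the top cell of each library the Cxcl2 ratio was 1.20. Of 17 NF-kB and inflammatory cytokine genes 13 were lower, with a median of -0.35 (percentile 0.14), led by Nfkb1 (-0.89) and Tnfaip3 (-0.51). Csf2 and Cxcl2 belong to this list too and are among its 4 higher members. Igf1r (-2.11), Nin (-1.75), Smad4 (-1.42) and Hsp90aa1 (-1.15) were lower.

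**Figure D3:**
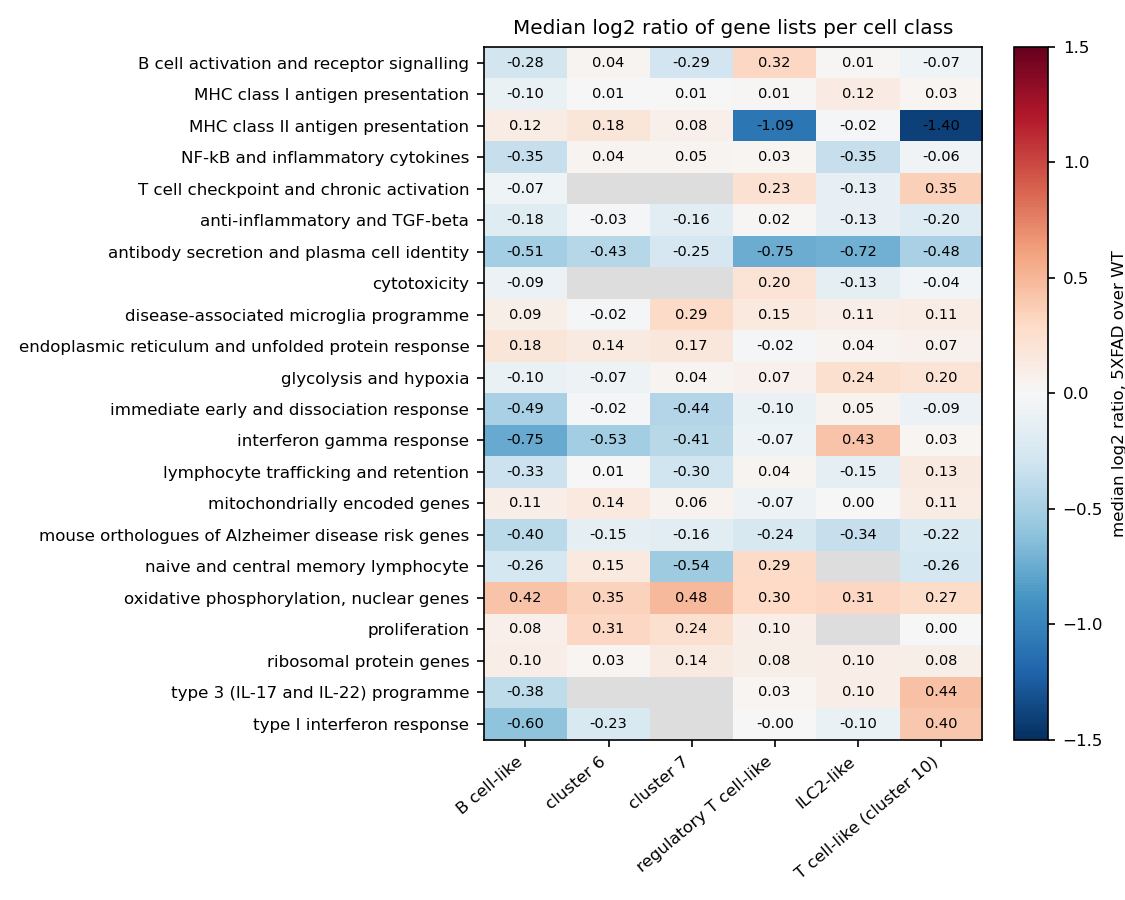
Median log2 ratio, 5XFAD over WT (colour and number), of each gene list (rows) in the 6 main classes (columns); grey cells had fewer than 5 measured members. Nuclear oxidative phosphorylation genes were above 0 in every class (0.27 to 0.48), while the immediate early list ranged from -0.49 to 0.05.

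The label check found Xist in both libraries, at 1154 CPM in 5XFAD and 1441 in WT, and 0 UMIs of 4 Y-linked genes in each, which allows at most 0.161 and 0.167 CPM. Mouse App (116 and 111 UMIs) and Thy1 (944 and 1047) had ratios of 0.01 and -0.20; the transgenes are human sequence, so these loci do not check the genotype.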

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

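All explanation tests in this part were chosen after the results were seen. The values below are the gene highest in 5XFAD, by the rule for named genes, in each class outside the 6 main classes, and a gene with opposite directions in 2 main classes by at least 1 on the log2 scale, both intervals excluding 0, that passed the filters on level and gene type of that rule in both. A stricter bound for opposite directions, run first, returned no gene, and the bound planned first was restored.

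Klf2, a transcription factor of lymphocyte trafficking, had a log2 ratio of 1.11 (0.82 to 1.40) in regulatory T cell-like cells and -1.01 (-1.25 to -0.77) in cluster 7. In the other main classes it was -0.32 (-0.37 to -0.28) in B cell-like cells, 0.02 (-0.17 to 0.21) in cluster 6, 0.42 (0.15 to 0.68) in T cell-like cells of cluster 10 and 1.16 (0.65 to 1.69) in ILC2-like cells. In ILC2-like cells its 151 CPM in 5XFAD was below the share of its highest class level that the filter asks for, and the unthinned shares of cells with a UMI were 23.3% in 5XFAD and 24.1% in WT. The difference between the classes was not tested.

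In ILC3-like cells Il22, which encodes the epithelial barrier cytokine IL-22, had a log2 ratio of 2.56 (2.39 to 2.73), with 2609 UMIs in 20 of 25 cells of 5XFAD, 620 of them in 1 cell, and 325 in 13 of 17 cells of WT. Cxcl10 had a ratio of 2.43 (1.89 to 3.02) in gamma delta T cell-like cells and 1.85 (1.35 to 2.38) in NK or ILC1-like cells, from 28 cells with a UMI in each class in 5XFAD and 9 and 15 cells in WT. A single 5XFAD cell held 65 of 261 and 72 of 170 UMIs. Cct6a in cluster 14 had a ratio of 1.60, with 53 of 263 UMIs in 1 cell. Gzma in cluster 11 had a bound of 4.79, but 99 of its 104 UMIs were in 1 cell, and the bound of 6.33 for Apod in cluster 15 came from 1 cell.

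Nuclear oxidative phosphorylation genes, which have short transcripts, were higher in 5XFAD in all 6 main classes. Over 9078 genes the log2 ratio fell with transcript length (Spearman rho -0.336 across genes, which are not replicates), and lists matched on length and expression had a median of 0.13. The oxidative phosphorylation list lay 0.30 above them, more than 2 SD of matched medians (SD 0.085). Transcript length as matched here thus accounted for part and not all of this difference. How close the matched genes came in length was not checked, so some effect of length may remain. The list's median was at least 0.27 in each of the 6 main classes, which is consistent with a difference between whole libraries; genotype and preparation cannot be told apart because each genotype is 1 library.

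Lower heat shock and immediate early genes in 5XFAD B cell-like cells may come from handling, from cluster 5 or from the different gene limits. The highest median in the other main classes was 0.054 in ILC2-like cells, against -0.49 in B cell-like cells. This argues against handling that lowers the list by the same amount in every class. It cannot speak against handling that acts on the classes to unlike degrees. The list's median was also below 0 in cluster 7 (-0.44, percentile 0), regulatory T cell-like (-0.10, percentile 3.13) and T cell-like cells (-0.09, percentile 4.97). In cluster 6 its median was -0.02 (percentile 25.5). Relative to lists matched on length and expression it was -0.41 in cluster 7 (percentile 0). It was -0.09 in regulatory T cell-like (percentile 11.9) and -0.06 in T cell-like cells (percentile 22.6). In cluster 6 it was -0.04 (percentile 30.5) and in ILC2-like cells 0.12 (percentile 95.1). Of these classes only cluster 7 thus stayed clearly low after matching on length. Without cluster 5 the median was -0.30, below random lists of the same cells by more than 2 SD (percentile 0.145), and with a common limit of 2500 genes it was -0.50, so neither accounts for the whole. Handling that acts on B cells alone or on the classes to unlike degrees, and a difference due to genotype, were not tested and stay open.

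B cell transcripts (7 genes) in T lineage and innate lymphoid cells were lower in 5XFAD by a log2 ratio of -1.33 (-1.42 to -1.23). In WT 45.9% of these UMIs were in the top 5% of cells, above the 12.5% that was the highest of 1000 draws by cell depth, so evenly spread free RNA cannot be the whole source. Without the top 5% of cells per library the ratio was -0.91 (-1.02 to -0.79), so those cells alone are not the whole source. Cells rich in B cell transcripts may reach past that cut, since 80 of 415 WT and 28 of 499 5XFAD T lineage cells gave an isotype call, so doublets stay open, as does a mixture of both.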

How the results depend on the processing

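Centring on the other classes, matching of lists on transcript length, the common gene limit, removal of cluster 5, of top cells and of cells with high doublet scores were chosen after seeing the data; the cause of a change was not tested unless stated. No paired analysis was possible because each genotype has 1 library. Removal of called doublets was not run, since the caller marked only 0.29% of cells, and the stricter cell filter removed 0 cells.

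Of 1742 values under alternatives 103 changed sign, of which 13 started from a gene ratio whose interval excluded 0 or a list median farther from 0 than 2 SD of random medians; these 13 follow. Relative to the median ratio of the same gene in the other classes, Atp5md was -0.10 and Bcl11a 0.054 in cluster 6, Hopx -0.059 in regulatory T cell-like cells, Csf2 -1.12 in ILC2-like cells, and Cd40lg -0.28 and Hspa1a 0.84 in cluster 10. By the same centring Ighm was 0.37 in B cell-like cells, 0.34 in cluster 6, 0.27 in cluster 7 and 0.016 in ILC2-like cells, and Igha 0.48 in cluster 6. Hspa1a in cluster 10 was 0.040 without the top cells, and the B cell activation list in cluster 7 was 0.032 with at least 200 UMIs per gene. More values moved without such a reversal. Centred on the other classes, 20 gene ratios stayed inside their counting interval, 28 left it and 11 reversed. Under TMM scaling 83 list medians stayed within the SD of random medians and 44 moved by more.

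In B cell-like cells, median-of-ratios and TMM scaling gave -0.26 and -0.25 for Cxcr4, -0.20 and -0.20 for the trafficking list, -0.48 and -0.47 for the type I interferon list, -0.36 and -0.35 for the immediate early list and 0.55 and 0.56 for oxidative phosphorylation; TMM gave -0.38 for the antibody list. Relative to random lists matched on length as well as expression, oxidative phosphorylation was 0.30. Without cluster 5, Cxcr4 was -0.22, the trafficking list -0.21 and the immediate early list -0.30; the last was -0.59 in thinned cells. Removal of cluster 5 took 6 of the B cell-like gene ratios outside their counting interval and left 4 inside. The T lineage share ratio was 0.012 without B cell-like cells. Shares with a Cxcr4 UMI were 56.3% (5XFAD) and 62.8% (WT) unthinned and 25.9% and 31.3% at 1500 UMIs, with 5XFAD lower at each depth.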

Other observations

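In the independent clustering of both libraries, which used no alignment between them, the B cells separated largely by library: 1 cluster held 1297 cells of 5XFAD and 54 of WT, and another 103 and 1047. T lineage and innate lymphoid clusters held both libraries, such as 130 and 114 cells in the regulatory T cell cluster and 128 and 107 in the ILC2 cluster. The deposited clusters do not show this separation to the same degree, and no explanation was tested.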
